A study of Homo sapiens with 12 samples.

How the data were processed

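Ribosome-protected fragments of HBEC3-KT cells with U2AF1 wt/wt or wt/S34F were measured in 12 libraries: monosome and disome footprints of both genotypes, with 3 replicates each. Per the labels' protocols, cells were treated with cycloheximide, lysates were digested with RNase I and ribosomes were pelleted through a sucrose cushion. Footprints were then ligated to adapters, reverse transcribed, amplified and selected by size. The series' design text calls the replicates biological. It names no batch, lane or day.

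The deposited file was a gene coverage matrix. The authors' values are mean per-base read coverage (signal) per gene, made with StringTie on hg19, per the submitters' processing notes. The versions, the aligner, the trimming of adapters and the removal of ribosomal RNA were not given in the sources used here. No scaling of the deposited coverage to depth is named in the sources used here, and none was tested for. The column sums differed 7.57-fold. Mean coverage divides by length, so the summed coverage of a library is not proportional to its reads. The 12 columns were matched to the samples by genotype, fraction and replicate number in their names, and 0 columns were left unmatched.

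The order of the rows was checked before any test. The columns held between 57742 and 57749 values, and the ID column held 57744 IDs, of which 57736 were distinct. Every column ended in a run of zeros written in another format, and the rows before that run were taken as the listed rows of the library. The IDs were set against these runs by finding the row at which the ID list starts over. After that row, more IDs have their nearest number among the first 3000 IDs. Over 1500 rows on each side the share was 11.8% before and 29.9% after row 31401. The zeros of wild-type monosome replicate 1 began 6 rows later, at row 31407. The zeros of the other 2 columns with as many values as IDs began 2130 and 5489 rows away. The zeros of S34F disome replicate 3 began 52 rows away, but that column held 57748 values against 57744 IDs. The IDs were therefore taken as those of wild-type monosome replicate 1, the column that matched best on both counts. In that library ENSG00000243655 held 95.7% and ENSG00000225840 held 0.953% of summed coverage, under this reading of the ID column. No order of IDs was available for the other columns, and their rows were not realigned, since any match by value would be a guess.

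The gene-level analysis fixed before the data were examined was not run. It consisted of limma fits on log2 values for 5 contrasts and camera tests of nuclear-encoded mitochondrial genes for 3 of them, which makes 8 results, with 108 other settings listed for them. It also included 35 gene lists and a rule for naming genes. That rule took the 10 genes of largest fold change in each direction among genes past an adjusted p of 0.05, members of each list, U2AF1, U2AF2 and XBP1. All of these need a row to hold one gene in every library. The filter of that plan, a share of at least 1e-06 of the summed coverage in at least 3 libraries, was applied only to count rows. The names of genes were not assigned either: of 59792 genes in the reference table used here, 0 carried an Ensembl ID.

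Measures that can be taken within a column, without matching its rows to genes, were computed per library instead. They were summed coverage, listed rows, rows above 0, rows with coverage of 1 or more, the median of rows above 0, the shares of the highest and of the 10 highest rows, and the exponential of the Shannon entropy. These 8 measures were chosen after the data were examined, from 21 statistics looked at for each library. Blank cells at the end of a column were taken as 0. Shares were compared in percentage points and other measures as log2 values, without a pseudocount. Each measure was tested in 6 contrasts: genotype within each fraction, fraction within each genotype, fraction over both genotypes, and the genotype by fraction interaction. The contrast over both genotypes was added after the data were examined. Tests were exact two-sided permutation tests of the difference in means. Libraries were dealt again between groups in 20 arrangements for 3 against 3, and in 400 for the last 2 contrasts, within genotypes or within fractions. The smallest p is 0.1 for the former and 0.005 for the latter. The null of the interaction test is that genotype has no effect in either fraction. P values were adjusted over all 48 tests by the Benjamini-Hochberg method, with a threshold of 0.05.

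The agreement of row order was measured by the overlap of rows above 0 and by Spearman correlations over rows and over bins. Bins held the log10 of summed coverage plus 0.001. Bin counts of 100, 200 and 500 were all tried. The early and late windows, 0% to 4% of the listed length and 3.5 percentage points from 68% on, were set after the places of the leading rows had been seen. Their 6 tests were adjusted on their own, outside the 48. The alternatives, all chosen after seeing the data, were other thresholds for a covered row, other numbers of leading rows, the inverse Simpson index, the highest row left out, wider windows, a replicate block and leaving out each library.

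The row-order measures and the exact test were tested on simulated data. In a simulated table of 50000 genes joined by gene, shared rows were 6.26 times the number expected by chance and the Spearman correlation over rows was 0.662. The share of covered rows in the simulated table was not matched to the libraries. A joined table of these libraries need therefore not reach 6.26. With each simulated column in its own order the multiple was 0.997, the correlation over rows was 0.0880 and the correlation of bins along the listed length was 0.420. The exact test over 400 arrangements called 100% of 400 simulated sets with a log2 shift of 2 (SD 0.5) and 3.75% of 400 sets without a shift. Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

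Whether equal replicate numbers pair the libraries could not be checked over genes. Over libraries, the deviations of log2 summed coverage from the group means correlated at 0.988 between monosome and disome libraries of the same number. The main tests used no pairing, and the series' design text does not say that a number marks a shared lysate or day.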

Results

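Ribosome footprints were sequenced from HBEC3-KT cells, an immortalised line of human bronchial epithelial cells. The cells carried either 2 wild-type alleles of U2AF1 or 1 wild-type and 1 S34F allele. U2AF1 is the small subunit of the splicing factor that binds the 3′ end of introns, and S34F is a recurrent cancer-associated substitution in it. Monosome footprints are the RNA fragments shielded by a single ribosome, and disome footprints are the longer fragments shielded by a pair of adjacent ribosomes. The title of the series concerns U2AF and the mRNAs of mitochondrial proteins encoded in the nucleus. The 12 libraries formed 4 groups of 3 biological replicates: wild-type monosome, S34F monosome, wild-type disome and S34F disome.

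The deposited matrix gave mean per-base read coverage, with 1 column per library and 57749 rows. The summed coverage of a library ran from 122654 in S34F disome replicate 1 to 928406 in S34F disome replicate 3, a 7.57-fold range. It was 173408, 399554 and 483123 in the wild-type monosome replicates and 172246, 218475 and 767478 in the S34F monosome replicates. It was 197990, 428033 and 524522 in the wild-type disome replicates and 122654, 192732 and 928406 in the S34F disome replicates. No read totals were used, so read depth is unknown and no counting interval could be given. No pair of the 12 libraries held identical values.

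Rows of different columns did not hold the same gene, so no value could be compared between libraries gene by gene. Each column listed a run of rows that differed in length between libraries and was followed by zeros to its end. The highest row of the 6 monosome libraries fell on 6 different rows, between rows 24469 and 36406. Divided by each column's own listed length, those places lay between 77.9% and 78.6%. In the 6 disome libraries the highest row fell on 6 rows between 16915 and 22128, which was 70.1% to 70.6% of the listed length. Among the 12 pairs of replicates of a group, the number of rows with coverage in both libraries was 1.01 times the number expected by chance (median, range 0.969 to 1.03). For rows with coverage of 1 or more, the 12 pairs together shared 215 rows, against 189 expected by chance. The median Spearman correlation over rows was 0.103 (range 0.0406 to 0.171, across rows, which are not independent replicates).

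**Figure D1:**
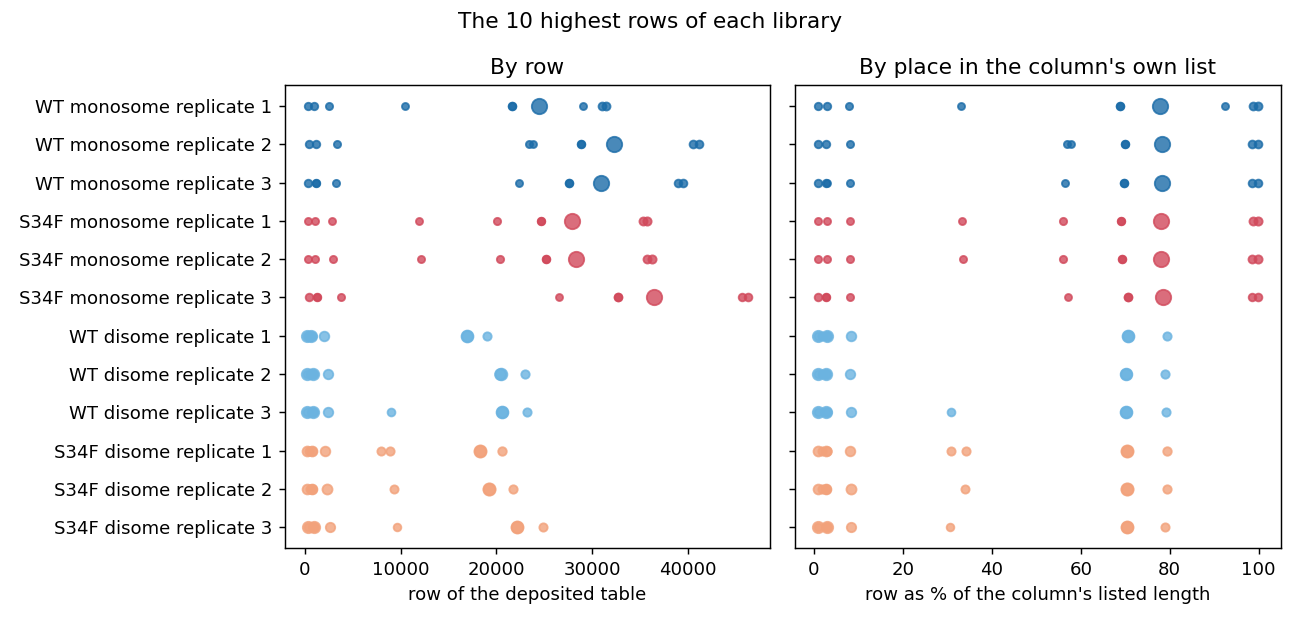
Place of the 10 highest rows of each of the 12 libraries, by row of the deposited table (left) and by row as a percentage of the column's own listed length (right). Larger points hold more of the library's summed coverage. The highest monosome rows spread from row 24469 to row 36406 on the left and lie at 77.9% to 78.6% on the right.

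Coverage was summed in 100 consecutive bins to set the order of the columns side by side. With bins cut at the same rows, the median Spearman correlation between replicates was 0.115. With bins cut along each column's own listed length it was 0.722, and with 1 column turned round it was 0.194. All of these fell with finer bins. With 200 bins the medians were 0.0533, 0.525 and 0.0122, and with 500 bins they were 0.0152, 0.221 and -0.0126. The filter planned for the gene-level test left 4 rows for the 6 monosome libraries, although each library alone had 541 to 732 rows past it. It left 138 rows for the 6 disome libraries, each of which alone had 1284 to 2473. No row passed in all 6 libraries of either fraction. Changes of single genes, of the mRNAs of nuclear-encoded mitochondrial proteins and of U2AF1 itself are therefore not reported. The comparisons below use measures of each library that do not depend on which row holds which gene.

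The first question was how coverage was spread over rows in the monosome and disome libraries. Monosome coverage was concentrated in a single row. That row held 96.1% ± 0.329 (SD, n = 3) of the summed coverage in wild-type cells and 95.7% ± 0.295 (SD, n = 3) in S34F cells. In the disome libraries the highest row held 23.6% ± 1.32 (SD, n = 3) and 27.8% ± 1.64 (SD, n = 3), in wild-type and S34F cells respectively. The 10 highest rows together held 99.1% ± 0.107 (SD, n = 3) of wild-type monosome coverage and 99.1% ± 0.164 (SD, n = 3) of S34F monosome coverage. They held 88.7% ± 0.967 (SD, n = 3) of wild-type disome coverage and 82.6% ± 9.01 (SD, n = 3) of S34F disome coverage. These are shares of summed per-base coverage, not of reads, so a short feature weighs more than a long one with as many reads. Whether the leading rows hold mRNAs was not determined. The shares therefore need not describe how ribosomes were spread over mRNAs.

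The share of the highest row was lower in disome than in monosome libraries over both genotypes, by a difference of -70.2 percentage points (exact permutation test within genotypes, two-sided p = 0.005, adjusted p = 0.04). The share of the 10 highest rows was lower by 13.5 points on average (a difference of -13.5, exact p = 0.005, adjusted p = 0.04). Both differences had the same direction in all 6 disome libraries against the monosome libraries of their genotype. The highest row lay at 77.9% to 78.6% of the listed length in monosome and at 70.1% to 70.6% in disome libraries. These places argue against a shared feature, so the first difference sets shares of different rows against each other. The value 0.005 is the smallest that the 400 arrangements of this test can give. The adjusted p of 0.04 was shared by 6 measures that all stood at this value. Fewer measures at this value would have raised the adjusted p. Several of the measures overlap in what they describe, and the 10 highest rows include the highest row, so they are not separate findings. Within 1 genotype, 3 libraries against 3 cannot give an exact p under 0.1, and both genotypes reached that value for both shares. With libraries paired by replicate number, the exact test over both genotypes gave 0.0312 for both shares, the smallest possible. Adjusted over 48 paired tests this was 0.25. The smallest p values of the paired tests leave them unable to pass the threshold after adjustment, so this outcome decides nothing.

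**Figure D2:**
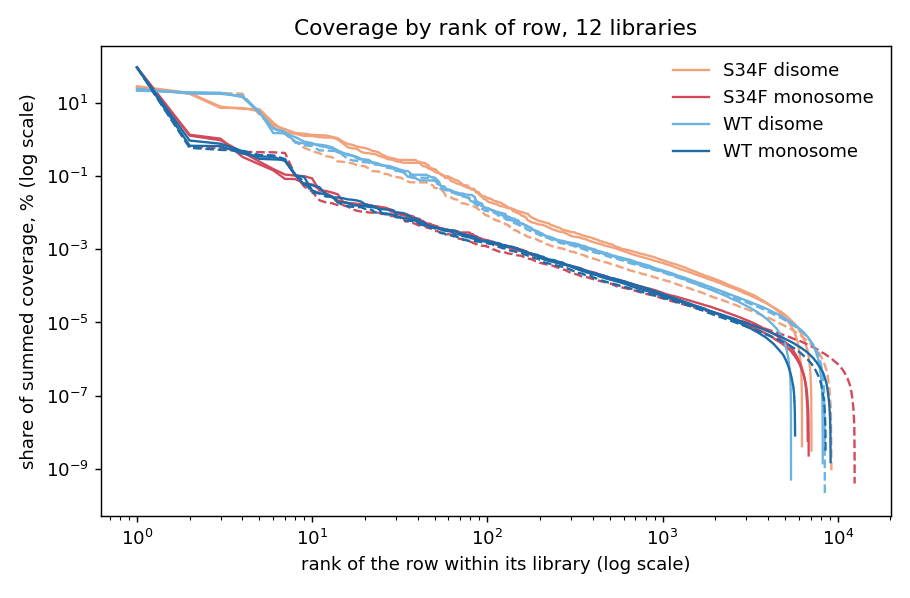
Share of summed coverage (%, log scale) against the rank of the row within its library (log scale) for the 12 libraries, 1 line each, coloured by group, with replicate 3 of each group dashed. The monosome lines start at about 96% and fall steeply after the highest row, while the disome lines start between 22.1% and 29.3%.

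More rows were well covered in disome libraries. A coverage of 1 or more was reached by 308 ± 82.0 rows (SD, n = 3) in wild-type monosome and 303 ± 134 rows (SD, n = 3) in S34F monosome libraries. In disome libraries it was reached by 953 ± 285 rows (SD, n = 3) in wild-type and 937 ± 264 rows (SD, n = 3) in S34F cells. The ratio of disome to monosome was 3.13 over both genotypes (log2 difference 1.65, exact p = 0.005, adjusted p = 0.04), and every disome library exceeded every monosome library of its genotype. The median coverage of rows above 0 was 4.82 times as high in disome libraries (log2 difference 2.27, exact p = 0.005, adjusted p = 0.04). It was 0.0175 ± 0.00192 (SD, n = 3) in wild-type monosome and 0.0856 ± 0.0102 (SD, n = 3) in wild-type disome libraries. In S34F cells it was 0.0178 ± 0.00419 (SD, n = 3) in monosome and 0.0829 ± 0.00711 (SD, n = 3) in disome libraries. A read of a longer fragment covers more bases, and disome fragments are longer. The highest row also took 96.1% of wild-type and 95.7% of S34F monosome coverage, which leaves less for the other rows. How far these points set both ratios was not tested.

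The listed rows were fewer in disome libraries. They numbered 37373 ± 5236 (SD, n = 3) in wild-type monosome and 27451 ± 3038 (SD, n = 3) in wild-type disome libraries, and 39461 ± 5946 (SD, n = 3) and 28247 ± 2871 (SD, n = 3) in S34F cells. The log2 difference between the fractions was -0.46 (exact p = 0.005, adjusted p = 0.04). The number of rows with any coverage above 0 did not differ detectably between the fractions (log2 difference -0.12, exact p = 0.55, adjusted p = 0.943). It was 7778 ± 1815 (SD, n = 3) in wild-type monosome, 7354 ± 1687 (SD, n = 3) in wild-type disome, 8686 ± 3291 (SD, n = 3) in S34F monosome and 7513 ± 1519 (SD, n = 3) in S34F disome libraries. That direction turned when a threshold was set, with a log2 difference of 1.24 for rows with coverage of 0.1 or more. Summed coverage did not differ detectably either (log2 difference 0.00218, exact p = 0.995, adjusted p = 1).

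The effective number of rows is the number of equally covered rows that would give the same Shannon entropy. It was 1.34 ± 0.0278 (SD, n = 3) in wild-type monosome and 1.36 ± 0.0232 (SD, n = 3) in S34F monosome libraries. In disome libraries it was 11.7 ± 0.642 (SD, n = 3) in wild-type and 16.2 ± 6.25 (SD, n = 3) in S34F cells. The ratio of disome to monosome was 9.87 (log2 difference 3.30, exact p = 0.005, adjusted p = 0.04). This ratio rested on the highest row: with that row left out of each library the log2 difference turned to -0.65 (exact p = 0.05).

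**Figure D3:**
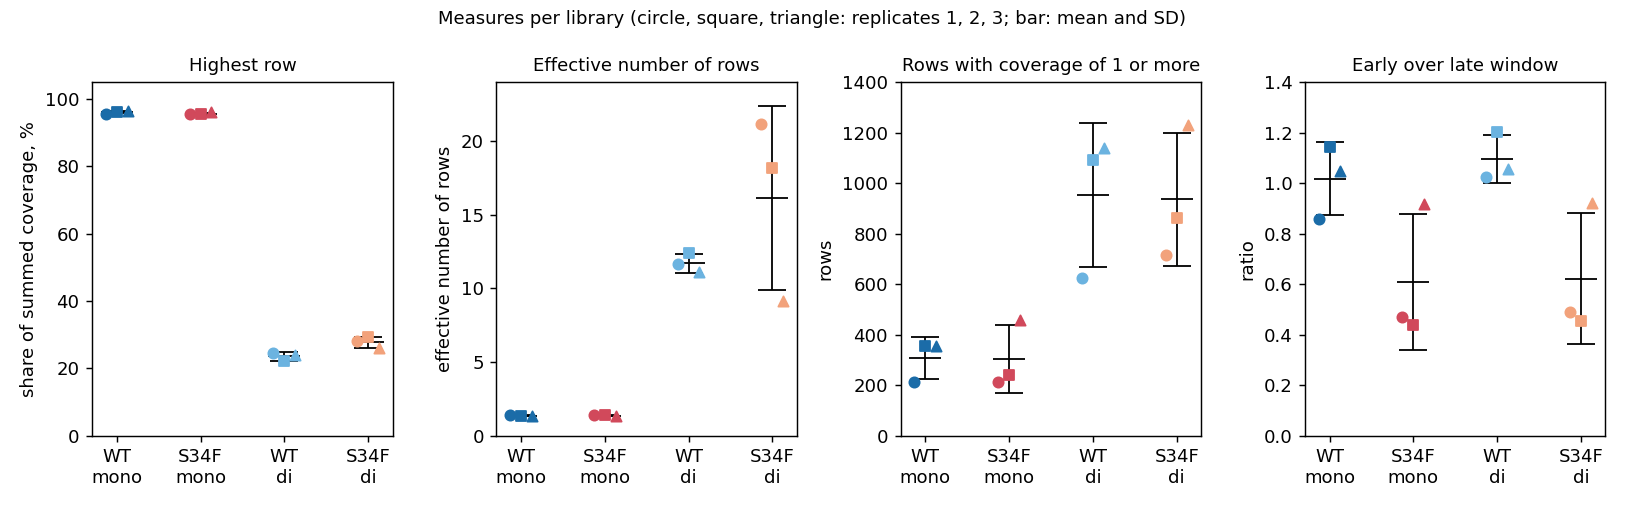
Share of the highest row (%), effective number of rows, number of rows with coverage of 1 or more, and ratio of coverage in an early to a late window of the column, for each library (points, shaped by replicate) with the mean and SD of each group of 3. Monosome libraries lie at 95.5% to 96.3% in the first panel and disome libraries at 22.1% to 29.3%.

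The second question was whether S34F cells differed from wild-type cells within a fraction. In monosome libraries none of the 8 measures separated the genotypes, and the smallest exact p was 0.2, for the share of the highest row (S34F minus wild type -0.355 points, adjusted p = 0.457). With the highest row left out, the effective number of rows was lower in S34F monosome libraries (log2 difference -0.32, exact p = 0.1, the smallest possible), against a log2 difference of 0.020 with it (exact p = 0.5). In disome libraries the highest row held a larger share in S34F cells. It held 28.0%, 29.3% and 26.0% in S34F disome replicates 1, 2 and 3 and 24.6%, 22.1% and 24.1% in the wild-type replicates. The difference was 4.19 points, with no overlap between the groups (exact p = 0.1, the smallest possible, adjusted p = 0.24). Chance gives such a separation of 3 from 3 libraries in 10% of cases. The 10 highest rows held 75.8%, 79.1% and 92.8% in S34F disome replicates 1, 2 and 3, against 87.7% to 89.6% in wild type (difference -6.12 points, exact p = 0.4, adjusted p = 0.768). This difference was -11.2 points without S34F disome replicate 3 and -2.74 points without S34F disome replicate 1. The effective number of rows was 21.1, 18.2 and 9.14 in the same 3 libraries and 11.1 to 12.4 in wild-type disome libraries (log2 difference 0.38, exact p = 0.4, adjusted p = 0.768). The log2 difference was 0.74 without S34F disome replicate 3 and 0.14 without S34F disome replicate 1.

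The numbers of rows with coverage of 1 or more were nearly equal between the genotypes. The log2 difference, S34F minus wild type, was -0.067 in monosome (exact p = 0.9, adjusted p = 1) and -0.010 in disome libraries (exact p = 1, adjusted p = 1). Leaving out 1 library at a time moved these values between -0.41 and 0.15 and between -0.29 and 0.16. With 3 libraries against 3 the exact p cannot fall under 0.1, so no difference of any size could pass the threshold in these tests.

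The third question was whether the genotype difference was the same in both fractions. The difference in the share of the highest row was 4.54 percentage points larger in disome than in monosome libraries (exact permutation test over 400 arrangements, p = 0.01). After adjustment over the 48 tests it missed the threshold (adjusted p = 0.0686). Without wild-type disome replicate 2 the difference was 3.80 points (exact p = 0.055). With the libraries paired by replicate number it was the same 4.54 points, with an exact p of 0.1, the smallest that the 20 arrangements of that test can give. The other 7 measures gave exact p values from 0.355 to 0.915 for this difference between differences. The null of the tests over 400 arrangements is that genotype has no effect in either fraction. They cannot decide whether the genotype difference is the same in both. For the highest row, the disome difference alone was 4.19 points, while the monosome share lay between 95.5% and 96.3%, near its upper limit. The highest rows of the fractions also lay at different places of the listing.

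Some leading rows recurred at the same place of every listing, which allowed 2 windows of the listing to be compared within a library. The early window, from 0% to 4% of the listed length, held 41.5%, 44.3% and 42.7% of summed coverage in the wild-type disome replicates. It held 22.6%, 22.0% and 41.7% in the S34F disome replicates 1, 2 and 3. The late window, 3.5 percentage points long from 68%, held 36.9% to 40.4% in wild-type disome and 45.2% to 48.6% in S34F disome libraries. In every disome library this window contains the highest row, at 70.1% to 70.6% of the listed length. The genotype difference in this window is therefore not separate from that in the share of the highest row. In monosome libraries both windows were small, at 0.271% to 1.04% and 0.574% to 1.14%. The ratio of early to late was 1.02 ± 0.145 (SD, n = 3) in wild-type monosome and 0.609 ± 0.268 (SD, n = 3) in S34F monosome libraries (exact p = 0.2, adjusted p = 0.6). It was 1.10 ± 0.0943 (SD, n = 3) in wild-type disome and 0.622 ± 0.261 (SD, n = 3) in S34F disome libraries (exact p = 0.1, the smallest possible, adjusted p = 0.6 over 6 tests). S34F replicates 1 and 2 gave 0.471 and 0.438 in monosome and 0.490 and 0.454 in disome libraries. S34F replicate 3 gave 0.917 and 0.923, against wild-type ranges of 0.859 to 1.14 and 1.03 to 1.20. Within the 6 pairs of monosome and disome libraries of the same genotype and replicate number, the ratio was higher in the disome library in 6, by 1.01 to 1.20 times. The exact p for disome against monosome over both genotypes was 0.0312 with the libraries paired in this way, the smallest that 6 pairs can give (adjusted p = 0.188 over 6 tests). It was 0.6 without the pairing (exact test, adjusted p = 0.84). Under the reading of the ID column, wild-type monosome replicate 1 had ENSG00000200169 and ENSG00000199347 among the leading rows of the early window. The late window of that library had ENSG00000200156 and ENSG00000199568. No gene name was assigned to these IDs, and the IDs in the windows of the other libraries were not determined.

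Monosome and disome libraries of the same genotype and replicate number had related totals. Over the 6 such pairs, log2 summed coverage correlated with Pearson's r = 0.980 (exact permutation p = 0.00417) and Spearman's rho = 0.943 (exact permutation p = 0.0167). Without the 2 pairs farthest from the median monosome total, r was 0.977. The ratio of early to late window in monosome and disome was 0.471 and 0.490, 0.438 and 0.454, and 0.917 and 0.923 in S34F replicates 1, 2 and 3. It was 0.859 and 1.03, 1.14 and 1.20, and 1.05 and 1.06 in the wild-type replicates, where the gap within replicate 1 was as wide as that between wild-type disome replicates. Its values fell into separate clusters, so no correlation is given for it. These are 2 of the measures, and pairing by number was not tested over genes.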

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

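All tests in this part were chosen after the results were seen. The genotype difference in the share of the highest row was 4.54 percentage points larger in disome than in monosome libraries (exact permutation p = 0.01, adjusted p = 0.0686). The null of this test is that genotype has no effect in either fraction, so it cannot decide whether the genotype effects differ. The highest row held 4.19 points more in S34F than in wild-type disome libraries and 0.355 points less in monosome libraries (S34F minus wild type -0.355). The monosome share lay between 95.5% and 96.3% in all 6 libraries, which leaves little room for a difference on this scale. The highest row lay at 77.9% to 78.6% of the listed length in monosome and at 70.1% to 70.6% in disome libraries. These places argue against a shared feature, so the contrast between the fractions sets shares of different rows against each other. The adjusted p missed the threshold, and no explanation was tested.

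The rows of different columns did not line up. A candidate explanation is that each column keeps the gene order of its own library and that the columns were placed side by side without a join on the gene. The places of the highest monosome row spanned 0.686 percentage points once divided by each column's listed length, as that order would give. Coverage too low for replicates to share rows was tested on rows with coverage of 1 or more, well above the lowest values. The 12 replicate pairs shared 1.14 times the number of them that chance gives, with 0.932 times in monosome and 1.15 times in disome libraries, which argues against low coverage as the whole cause. No biological explanation was tested, since a group cannot move a gene to another row.

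S34F replicate 3 lay apart from S34F replicates 1 and 2 in the ratio of early to late window, and had the highest summed coverage of its group, in both fractions. Summed coverage may contribute. The slope of the log2 ratio on log2 summed coverage, from only 3 libraries each, was 0.0785 in wild-type disome and 0.241 in wild-type monosome. Within S34F it was 0.348 in disome and 0.493 in monosome. However, wild-type replicate 2 lay above replicate 3, of higher summed coverage, in both fractions. S34F replicate 2 likewise had a higher summed coverage than replicate 1 but a lower ratio. The ratio was 0.438 against 0.471 in monosome and 0.454 against 0.490 in disome. The rising S34F slopes thus rest on replicate 3, which is what was to be explained. A wrong label was set against 6 measures in each fraction, with mixed outcome: in disome, 3 lay beyond the wild-type range toward S34F replicates 1 and 2 (a highest row 1.43 points above any wild-type library, a late window of 45.2% and a ratio of 0.923), 1 lay within that range (an early window of 41.7%) and 2 lay beyond it on the other side (10 highest rows at 92.8%, effective number 9.14). The 3 toward S34F replicates 1 and 2 are not separate checks. The highest row, at 26.0%, lies in the late window, and that window is the divisor of the ratio. The 6 measures thus overlap, and their tally is not 6 separate outcomes. In monosome, 3 lay within the wild-type range. Another 3 lay beyond it but not toward S34F replicates 1 and 2, among them the late window at 1.14%. Summed coverage and a wrong label cannot be told apart with 3 libraries per group; a batch, which no label names, was not tested, and no biological explanation was tested either, since genotype is the same in these replicates.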

How the results depend on the processing

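All alternatives in this part were chosen after seeing the data. The 108 settings listed before the data were examined (pseudocount, filter, normalization, genes entering the scaling, replicate block, spread model, left-out replicates, libraries in the fit, inter-gene correlation) were not run, because a row does not hold one gene across libraries. Of 540 alternatives to 54 results, 434 kept direction and side of an unadjusted threshold of 0.05. Disome against monosome over both genotypes kept p under the threshold without any 1 library for listed rows, rows with coverage of 1 or more, median coverage, both shares and the effective number. Read depth is unknown, so what it limits was not measured. Except where stated, the cause of a change was not tested.

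The replicate block gave the share of the highest row in the interaction an exact p of 0.1 at the same 4.54 points; this is the smallest p of its 20 arrangements. For the early over late ratio, disome against monosome over both genotypes, it gave an exact p of 0.0312 at a log2 difference of 0.076 (adjusted p = 0.188 over 6 blocked tests; 0.6 without the block). At the unadjusted threshold it changed no other call. Over 6 pairs its smallest p is 0.0312, which the 6 measures with an adjusted p of 0.04 for disome against monosome over both genotypes all reached. Adjusted over 48 blocked tests this came to 0.25, so none of the 48 passed with the block; this floor leaves the test unable to pass. Monosome and disome libraries of the same number deviated together from their group means, at r = 0.988 for log2 summed coverage over 6 pairs. This is a hint from the data that the numbers pair the fractions, and summed coverage ranked the 3 numbers alike in all 4 groups. Neither could be tested over genes. Within 1 genotype or fraction the smallest p of the block is 0.25. The 2 highest rows gave the interaction 3.77 points (exact p = 0.06), and leaving out each library gave 3.79 to 5.42 points. The disome row of rank 2 lay in the early window in wild type but in the late window in S34F cells. The 2 highest rows therefore add rows from unlike places of the listing.

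The number of rows above 0 turned with its threshold. At 0.1 or more, disome against monosome gave 1.24 in wild type, 1.23 in S34F and 1.24 over both. At 1 or more the 6 contrasts gave -0.067 and -0.010 (genotype in monosome and disome), 1.62, 1.68 and 1.65 (disome against monosome in wild type, S34F and both) and 0.057 (interaction). At a share of 1e-05 or more of summed coverage, genotype in monosome gave -0.10, the fraction contrasts 1.43, 1.78 and 1.61, and the interaction 0.35. With the highest row left out, the effective number gave -0.32 for genotype in monosome (exact p = 0.1, the smallest possible) and -1.13, -0.16 and -0.65 for the fraction contrasts; the construction shows that this row set the direction. It moved genotype in disome from 0.38 to 0.66 and the interaction from 0.36 to 0.97, and the inverse Simpson index moved them to 0.083 and 0.073, none of these past the threshold. For genotype in monosome, the 2 highest rows gave 0.0101 points, and the 5 and 100 highest gave 0.143 and 0.000952 points.

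Leaving out 1 library turned some differences that lay within the spread of replicates. The ranges are log2 differences in the order genotype in monosome, genotype in disome, disome against monosome in wild type, S34F and both, and interaction, with those that did not turn left out. Rows above 0 ranged from -0.17 to 0.28, -0.17 to 0.16, -0.29 to 0.13, -0.32 to 0.13, -0.23 to 0.024 and -0.29 to 0.21. Summed coverage ranged from -0.73 to 0.35, -1.20 to 0.26, -0.31 to 0.56, -0.997 to 0.53, -0.43 to 0.33 and -1.13 to 0.39. For genotype in monosome, genotype in disome and interaction, listed rows ranged from -0.043 to 0.15, -0.053 to 0.10 and -0.13 to 0.085. Rows with coverage of 1 or more ranged from -0.41 to 0.15, -0.29 to 0.16 and -0.22 to 0.40, and median coverage from -0.18 to 0.12, -0.15 to 0.012 and -0.16 to 0.14. The early over late ratio ranged from -0.0039 to 0.20, -0.28 to 0.38, -0.085 to 0.25 and -0.40 to 0.26 for the fraction contrasts and the interaction. The share of the 10 highest rows ranged from -0.0996 to 0.0484 points for genotype in monosome.

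Leaving out S34F replicate 3 moved several genotype differences the most. The early over late ratio then gave -1.15 in monosome and -1.21 in disome, against -0.82 and -0.89 with it.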

Other observations

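The leading rows of the disome libraries gave a second view of S34F replicate 3, with no group formed from it. The effective number of rows was 9.14 in S34F disome replicate 3, below the 3 wild-type disome libraries at 11.1 to 12.4. S34F disome replicates 1 and 2 lay above them at 21.1 and 18.2. The library had the highest summed coverage of the 12, at 928406. In the monosome fraction the effective number of rows lay between 1.32 and 1.38 in all 6 libraries.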
